A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

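Total RNA of Saccharomyces cerevisiae was labelled with Cy3 and hybridised to 1-colour Agilent gene expression arrays, 1 sample per array. Per the labels, cultures were grown to mid-log phase (OD 0.6) and incubated at 30 °C for 30 min with or without 5 µM alpha factor. Samples were grouped by the labels into treated parents (2), untreated parents (2), treated segregants (43) and an untreated segregant (1). The labels do not say that arrays came from separately grown cultures beyond naming the strains, so p-values measure only the spread between these arrays, part of which may be technical.

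The deposited scanner files hold intensity values per spot. Per the file headers, the intensity is Cy3 brightness after background subtraction and spatial detrending by Agilent Feature Extraction 10.5.1.1, on array design 016322; the submitters' processing notes name Agilent Feature Extraction 9.1. Raw median spot intensity and local background intensity are also given, per the file headers, with no normalization between arrays. The other columns used, per the file headers, are 0 or 1 flags for spots well above background, saturated or outlying, and a control type. The authors' series matrix held the same processed intensity in 626304 of 626304 cells, on a linear scale with no centring, and was used as an alternative in which outlier spots were kept. No column lacked a sample.

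Each array held 13048 spots, of which 536 control spots were left out. The 12512 gene spots were 2 spots of 1 probe for each of 6256 genes, so no rule for several probes was needed. Outlier spots, 0 to 97 per array, were left out and 0 gene spots were saturated. The arrays lay on 6 slides of 8, with all parent arrays on slide 1 and both SEG8 arrays on slide 2. The duplicate spots had a median SD of 0.058 on the log2 scale (0.037 to 0.173 over arrays).

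The log2 of the processed intensity minus the 75th percentile of the array was averaged over spots. A gene entered the treatment and parent tests if it was well above background on at least 2 of 6 arrays (6252 genes, 4 removed), and the segregant tests if on at least 22 of 43 (6230 genes, 26 removed). A gene not well above background on all arrays of a group has only a bound there: the fold is then the mean of the brighter group over the mean, per array, of the higher of the lowest signal well above background and the dim value itself.

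Gene names are those of the array design, annotated on sacCer1 per the file headers. Of 6256 names, 5756 matched the reference table of assembly R64, used only for names, coding length and which genes neighbour each other; no coordinates are printed because the builds differ, and 500 names kept the form on the array. The chromosome is read from the systematic name.

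The effect of alpha factor was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on 6 arrays of S96, HS959 and SEG8, with strain as a term, since the labels give each strain once with and once without alpha factor; the changes of 2 strains correlated across genes with r of 0.80 to 0.85. This leaves 2 residual degrees of freedom plus 2.62 from the prior. The parents were compared in the same fit, assuming that their difference is shared by both conditions. Calls use Benjamini-Hochberg adjusted p under 0.05 throughout. Variance over segregants was tested one-sided with an F test against the moderated residual variance of the 6-array fit. Segregant and parental means were compared with limma. Shares of variable genes in lists were compared by Fisher's exact test. Gene lists were tested with limma's camera (preset correlation 0.01), with an estimated correlation, and with fry, over 21 lists: pheromone-induced, pheromone signalling, a-specific, alpha-specific, meiosis, filamentation, flocculin, G1/S, core histone, G2/M, M/G1, daughter-cell, ribosomal protein, ribosome biogenesis, general stress, cell wall integrity, amino acid synthesis, respiration, ergosterol, phosphate and iron genes. Some genes are in more than 1 list. With an estimated correlation, camera uses only the 2 residual degrees of freedom of the 6-array fit, so it could hardly call any list. Core histone and iron uptake genes had estimated correlations of -0.05 and 0.004, under the preset 0.01, and still lost their alpha factor calls. Correlations across segregants used 100000 permutations, and a score was called clustered where a mixture of 2 normal distributions (mclust 6.1.1) gained more than 10 in BIC over 1. Neighbouring genes were compared with 1000 random orders. A chromosome was listed where its median shift was at least 0.3 and over 5 times the median absolute deviation of that chromosome over segregants. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.

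Designs, lists and the rule for named genes were fixed before the data were examined: the 12 largest changes each way with alpha factor, the 8 largest each way between parents, the 15 largest SDs among segregants, up to 5 each way for the segregant mean, the 4 members of a described list with the largest change or SD, and always STE12, FUS1, AMN1 and FLO8. Other genes, such as the members that make up a count of 5 or fewer, exceptions within a list, genes at the ends of the nearer-parent count and genes near background in some segregants, were chosen after their values were seen. Results for some single genes are not reported.

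Each step was tested on simulated data with 200 changed genes. For alpha factor 97% of changes of 1 and 100% of changes of 2 (log2) were recovered, with 14 unchanged genes among 211 calls over 6252 genes; for the parents 92% and 99%, with 12 among 203. For segregant variance 98% of genes with an added SD of 1 were recovered and 28 unchanged genes were called over 6230, more than the nominal share. The count of variable genes is therefore too high. The simulation held no slide effect, so it cannot say by how much. Within slides 1150 genes passed, beside 1987 without regard to slide. For the segregant mean 98% of changes of 5 were recovered with 15 unchanged genes called.

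The alternatives were normexp background (offset 50), quantile and median scaling, other filters on dim probes, the series matrix values, a trended variance prior, leaving out each strain, no strain term, all treated against the untreated arrays, slide as a block or within slides, another noise estimate, other list tests, another threshold or parental value for the nearer-parent count, the treated parents as the reference for chromosome shifts, and removal of principal components. The files used have no mean spot signal, so normexp was run on median spot intensity. The brightest-probe alternative was not run, since each gene has 1 probe, and slide as a block was not run in the 6-array fit, where strain lies within slide.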

Results

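RNA of haploid MATa budding yeast was measured on 1-colour Agilent arrays carrying 6256 genes. MATa cells respond to alpha factor, the mating pheromone secreted by MATalpha cells. Of 48 arrays, 43 held segregants of a cross named YJM789 X S96 in the labels, each under its own name and treated with 5 µM alpha factor for 30 min. The parental lines S96 and HS959 were measured with and without alpha factor, on 2 treated and 2 untreated arrays, and segregant SEG8 was the 1 segregant also measured untreated. Array medians of the deposited intensity lay between 9804 and 23353, and 94.0% to 99.9% of gene spots were well above background, with segregant SEG14 the lowest. The number of arrays limits the precision: no strain was measured more than once in a condition. Levels are log2 intensity minus the 75th percentile of the array.

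The treated and untreated arrays of S96, HS959 and SEG8 showed which genes changed with alpha factor. Of 39 pheromone-induced genes 35 rose, and 27 of 30 G1/S genes and all 8 core histone genes fell. As lists they were called by camera with the preset correlation and by fry (fry adjusted p = 0.0107, 0.0153 and 0.00476). With an estimated correlation camera called none of them (adjusted p = 0.419 for each). That test had 2 residual degrees of freedom and could hardly call any list, here or below. PRM3, needed for nuclear fusion after mating, rose by 8.02 ± 0.70 on the log2 scale (SD over strains, n = 3), or 260-fold, and FUS2, needed for cell fusion, rose by 5.26 ± 0.19. The S-phase cyclin gene CLB6 fell by 5.71 ± 0.55 and the G1 cyclin gene CLN1 fell by 3.35 ± 0.15. In limma, 2223 of 6252 tested genes (35.6%) passed an adjusted p of 0.05, 941 higher and 1282 lower, all of them with the same sign in the 3 strains. A change of at least 2-fold was seen in 241 of the higher and 240 of the lower genes. The call count rests on few arrays: it was 1636 without S96, 842 without HS959 and 610 without SEG8, and 657 when strain was left out of the fit.

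Among the 12 genes with the largest increases, several encode membrane proteins of mating cells. PRM6 rose by 7.64 ± 1.14 and PRM2 by 6.43 ± 0.46, both named as pheromone-regulated membrane proteins. FIG1, part of the low-affinity calcium influx of mating cells, rose by 6.48 ± 1.52, with 4.75 in HS959 and 7.10 in S96. PRM1, which acts in plasma membrane fusion, rose by 5.93 ± 0.47. IME4, an mRNA methyltransferase gene known from meiosis, rose by 9.12 ± 0.59 from a low untreated level. The systematic reading frame YCL076W rose by 10.47 ± 1.12, the largest increase, and was above background on 2 of the 3 untreated arrays. The remaining increases were in YDR124W (5.67 ± 0.32), YPR027C (5.48 ± 0.48), YML047W-A (5.41 ± 1.15) and YDR241W (5.13 ± 0.59), which have no standard symbol on the array. Adjusted p in limma lay between 0.000369 for FUS2 and 0.00390 for FIG1 in this group of 12.

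The 12 largest decreases were led by cell cycle genes. PCL1, a G1 cyclin of the kinase Pho85, fell by 4.90 ± 0.70, and YOX1, a repressor of early cell cycle promoters, fell by 3.79 ± 0.48. The cohesin gene MCD1 fell by 3.71 ± 0.19, and NRM1, a co-repressor of G1/S genes, fell by 3.68 ± 0.32. TOS4 fell by 3.37 ± 0.39 and ACM1, an inhibitor of the anaphase-promoting complex, fell by 3.36 ± 0.37. Cell surface and glycosylation genes were also present: TOS6 fell by 5.51 ± 0.22, the mannosyltransferase gene MNN1 fell by 3.41 ± 0.37, CSS1 fell by 3.45 ± 0.66 and HPF1 fell by 3.34 ± 0.80. FUS1, a cell fusion gene used as a pheromone reporter, rose by 3.52 ± 0.22 (adjusted p = 0.000598). STE12, the transcription factor of the pathway, rose by 0.78 ± 0.41 (adjusted p = 0.0288), a call lost without S96 (0.59, adjusted p = 0.0702) or without SEG8 (0.74, adjusted p = 0.130). AMN1, an inhibitor of mitotic exit in daughter cells, rose by 1.25 ± 0.15 (adjusted p = 0.00261). FLO8, an activator of adhesion genes, changed by -0.43 ± 0.23 (adjusted p = 0.0452), past the threshold at this scaling but not with quantile (-0.35, adjusted p = 0.0873) or median scaling (-0.42, adjusted p = 0.0527), nor with normexp background (-0.38, adjusted p = 0.0532), without HS959 (-0.31, adjusted p = 0.181) or without SEG8 (-0.45, adjusted p = 0.151).

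**Figure D1:**
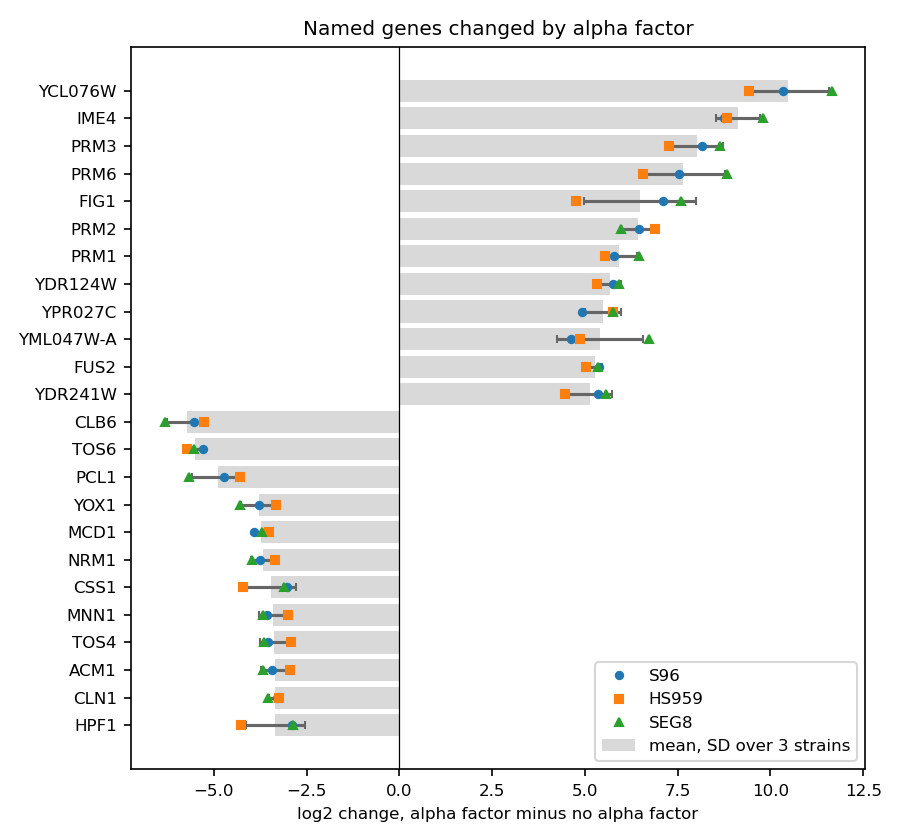
Change with alpha factor of the 12 genes with the largest increases and the 12 with the largest decreases; the horizontal axis is the log2 change, treated minus untreated, bars are the mean of 3 strains with the SD, and points are the strains. All 3 points lie on the same side of 0 for each gene, from 10.47 for YCL076W to -5.71 for CLB6.

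Of 39 pheromone-induced genes, 35 rose, 1 fell and 3 did not pass, and the mean change was 2.67 ± 0.31 (SD over strains, n = 3). PRM3, PRM6, FIG1 and PRM2 changed most. PRM7 was the 1 that fell, by 1.42 ± 0.35. PRM8 (2.39 ± 2.87), PRM9 (0.03 ± 1.04) and ECM18 (0.20 ± 1.19) did not pass. The list moved relative to other genes in limma's camera with a preset correlation (adjusted p = 8.43e-20), and adjusted p = 0.419 with an estimated correlation. Adjusted over the list alone, again 35 rose and 1 fell. Of 21 signalling components, 12 rose and 0 fell, with a mean of 0.61 ± 0.15 (camera adjusted p = 3.35e-05; adjusted p = 0.419 with an estimated correlation), and the count adjusted over the list alone was also 12. Examples were DIG2 (2.00 ± 0.15) and SST2 (1.56 ± 0.28), negative regulators of the pathway, the phosphatase gene MSG5 (1.80 ± 0.29) and the kinase gene FUS3 (1.40 ± 0.67).

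The lists fixed as markers of cell type also moved. All 7 a-specific genes rose, by 1.46 ± 0.34 on average (camera adjusted p = 6.70e-05; adjusted p = 0.419 with an estimated correlation), among them ASG7 (3.81 ± 0.65), the agglutinin subunit gene AGA2 (1.77 ± 0.73), BAR1, the protease that degrades alpha factor (1.59 ± 0.33), and the a-factor gene MFA2 (0.91 ± 0.28). Of 5 alpha-specific genes, normally active in MATalpha cells, 4 rose, with a mean of 1.99 ± 0.14 (camera adjusted p = 0.00350; adjusted p = 0.419 with an estimated correlation). The alpha-factor gene MF(ALPHA)2 rose by 5.05 ± 0.92, the agglutinin gene SAG1 by 1.91 ± 0.79, MF(ALPHA)1 by 1.57 ± 0.37 and the a-factor receptor gene STE3 by 1.32 ± 0.45, and AFB1 did not pass (0.11 ± 0.44). Adjusted over the list alone the counts were 7 and 4. Of 12 meiosis genes, 3 rose and 4 fell, the same over the list alone, and the list was not called (mean 0.16 ± 0.09, camera adjusted p = 0.891), although its median was -0.07. The recombinase gene DMC1 rose by 2.19 ± 0.28, SPO11 by 1.85 ± 0.12 and the meiotic activator gene NDT80 by 1.07 ± 0.09, and SPO13 fell by 1.17 ± 0.08.

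G1/S, core histone and ribosome biogenesis genes fell as lists. Of 30 G1/S genes, 27 fell and 0 rose, with a mean of -1.69 ± 0.19 (camera adjusted p = 3.64e-12; adjusted p = 0.419 with an estimated correlation), led by CLB6, PCL1, YOX1 and MCD1; 28 fell when adjusted over the list alone. All 8 core histone genes fell, by 1.70 ± 0.03 on average (camera adjusted p = 6.57e-06; adjusted p = 0.419 with an estimated correlation), over the list alone as well. HTB2 fell by 2.91 ± 0.66, HHF1 by 1.86 ± 0.30, HTB1 by 1.74 ± 0.14 and HHT1 by 1.68 ± 0.16. Of 42 ribosome biogenesis genes, 34 fell and 1, NOC3, rose, with a mean of -0.44 ± 0.09 (camera adjusted p = 2.20e-08; adjusted p = 0.419 with an estimated correlation); 39 fell and 1 rose when adjusted over the list alone. The helicase gene DBP8 fell by 0.94 ± 0.18, RRP12 by 0.72 ± 0.11, ERB1 by 0.65 ± 0.13 and IMP3 by 0.65 ± 0.19. The 138 ribosomal protein genes had a mean change of 0.04 ± 0.17, which was -0.01 with quantile scaling, and the list was not called (adjusted p = 0.0510). Of 19 G2/M genes, 8 fell and 2 rose (11 and 2 over the list alone), with no call for the list (mean -0.28 ± 0.07, adjusted p = 0.0815); the mitotic cyclin gene CLB1 fell by 1.43 ± 0.33 and the kinase gene DBF2 rose by 0.90 ± 0.13.

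Lists of nutrient uptake and stress genes were also called. Of 14 iron uptake genes, 11 fell and 0 rose (12 and 0 over the list alone), with a mean of -0.80 ± 0.05 (camera adjusted p = 0.000120; adjusted p = 0.419 with an estimated correlation). The siderophore transporter gene SIT1 fell by 1.90 ± 0.08, the iron permease gene FTR1 by 1.42 ± 0.15, the cell wall gene FIT3 by 1.16 ± 0.13 and ARN1 by 1.08 ± 0.37. Of 13 phosphate starvation genes, 8 fell and 1 rose (10 and 1 over the list alone), with a mean of -0.61 ± 0.09 (camera adjusted p = 0.0224; adjusted p = 0.543 with an estimated correlation). The phosphate transporter gene PHO84 fell by 2.64 ± 1.47, SPL2 by 1.96 ± 0.90 and the acid phosphatase gene PHO5 by 1.19 ± 0.34, whereas the regulator gene PHO81 rose by 1.32 ± 0.39. The phosphate call was lost without S96 (-0.56, adjusted p = 0.0627). Of 27 general stress genes, 11 rose and 3 fell, over the list alone as well (mean 0.31 ± 0.12, camera adjusted p = 0.00438; adjusted p = 0.419 with an estimated correlation). The glutamate decarboxylase gene GAD1 rose by 2.23 ± 0.47 and the glycogen phosphorylase gene GPH1 by 1.63 ± 0.48, and DDR2 fell by 1.30 ± 0.81 and YGP1 by 1.13 ± 0.26.

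The parents were compared as HS959 minus S96 over both conditions. HS959 carried far less signal for the asparaginase genes of the ASP3 cluster and for REE1, BDS1, PRM8 and PRM9. It carried more signal for the mitochondrial cytochrome oxidase genes COX1 and COX2 and for the flocculin gene FLO11. ASP3-4 differed by -13.83 (treated -13.99, untreated -13.67; limma adjusted p = 0.00142) and COX2 by 5.22 (treated 4.97, untreated 5.47; limma adjusted p = 0.000374), with n = 2 arrays per parent. Of 6252 genes, 1291 (20.6%) passed, 417 higher and 874 lower in HS959, all with the same sign in both conditions, and at least 2-fold in 138 and 342. With 1 probe per gene, a sequence difference at the probe could not be told apart from a difference in RNA, here or among the segregants. Quantile scaling moved the median of all genes by 0.13, from -0.09, and gave 706 higher and 608 lower. Without SEG8, which adds to the estimate of spread, 738 genes passed. The treated parents alone, 1 array each, were also set against the spread of the 43 segregants. That spread holds the parental difference itself (ASP3-4: SD 6.64 beside -13.99), so it could not show how many genes differ.

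The 4 ASP3 probes, of near-identical copies that could share signal, read -13.83, -13.81 (ASP3-1), -13.76 (ASP3-3) and -13.66 (ASP3-2). REE1 differed by -13.12 and was above background on 1 of the 2 HS959 arrays. BDS1, an alkyl sulfatase gene, was not well above background on either HS959 array and was at least 1491-fold lower there (limma adjusted p = 0.000228). PRM9 was at least 426-fold lower by the same bound (adjusted p = 0.00102), and its relative PRM8 differed by -11.47, with -14.00 treated and -8.94 untreated. The largest differences in the other direction, after COX2 at 5.22, were COX1 (5.17), YER187W (4.74), FLO11 (4.60), the transcription factor gene HMS1 (4.16), the peroxisomal thiolase gene POT1 (3.84), COS12 (3.78) and the vitamin B6 gene SNZ3 (3.63). FLO11 differed by 2.95 treated and 6.24 untreated (adjusted p = 0.0298), and its call was lost without SEG8 (adjusted p = 0.0617). AMN1 was lower in HS959 by the value -0.87 (adjusted p = 0.0119). STE12 (-0.06, adjusted p = 0.857), FUS1 (-0.06, adjusted p = 0.789) and FLO8 (0.22, adjusted p = 0.317) did not pass.

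Of 11 daughter-cell genes, 8 were lower in HS959 and 0 higher (9 and 0 over the list alone). Their mean was -2.24, with -2.48 treated and -2.0 untreated (camera adjusted p = 0.000104; adjusted p = 0.671 with an estimated correlation). DSE1 differed by -6.13, DSE2 by -5.51, the glucanase gene SCW11 by -3.42 and the chitinase gene CTS1 by -2.55. Of 13 phosphate starvation genes, 11 were lower and 0 higher (13 and 0 over the list alone), with a mean of -2.25, -2.16 treated and -2.34 untreated (camera adjusted p = 5.64e-06; adjusted p = 0.671 with an estimated correlation). SPL2 differed by -5.96, PHO84 by -4.97, PHO89 by -4.51 and PHO5 by -3.51. Of 37 amino acid synthesis genes, 11 were lower and 0 higher (15 and 0 over the list alone; mean -0.43, camera adjusted p = 0.00292; adjusted p = 0.671 with an estimated correlation), with MET6 at -1.91, HIS4 at -1.44, MET17 at -1.31 and ILV3 at -1.11. Of 34 nuclear respiration genes, 11 were higher and 1, FUM1, lower (13 and 1 over the list alone; mean 0.32, camera adjusted p = 8.97e-05; adjusted p = 0.671 with an estimated correlation), with CYC1 at 1.99, CYT1 at 1.39, RIP1 at 1.22 and QCR6 at 0.92.

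Differences between the parents were called for 5 further lists. Filamentation and adhesion genes had a mean of 0.69 (0.39 treated, 0.99 untreated) with 1 of 11 past the threshold (FLO11), as over the list alone (camera adjusted p = 0.00537; adjusted p = 0.671 with an estimated correlation). Flocculin genes had a mean of 1.88, with 0.47 treated and 3.30 untreated, so that their difference was not shared evenly by the conditions, and 1 of 5 past the threshold and 3 over the list alone (camera adjusted p = 0.0372; adjusted p = 0.671 with an estimated correlation), and lost the call with quantile scaling (adjusted p = 0.144). Ergosterol synthesis genes had a mean of 0.21 with 4 of 19 higher, and 4 over the list alone (camera adjusted p = 0.00742; adjusted p = 0.733 with an estimated correlation), with HMG1 at 1.01, ERG28 at 0.99 and ERG5 at 0.72. Ribosome biogenesis genes had a mean of 0.12, or 0.21 above the median gene, with 2 of 42 higher (DBP8 and ENP1) and 0 over the list alone (camera adjusted p = 0.00185; adjusted p = 0.733 with an estimated correlation). The 138 ribosomal protein genes had a mean of -0.33, or -0.24 relative to the median gene, with 3 lower (RPL13A, RPS4A and RPS6A) and 0 over the list alone (camera adjusted p = 6.37e-08; adjusted p = 0.761 with an estimated correlation); with quantile scaling their mean was -0.00 and the call was gone (adjusted p = 0.634). The 39 pheromone-induced genes were not called between the parents (mean -0.48, median 0.05, camera direction upward, adjusted p = 0.283), and 3 passed singly: CIK1 at -0.57, PRM8 and PRM9. No signalling component passed (mean 0.05, adjusted p = 0.189).

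Among the 43 treated segregants, 3 of 39 pheromone-induced genes varied past the threshold, and 9 of 11 daughter-cell, 11 of 13 iron uptake and 10 of 12 meiosis genes did. The SD among segregants was 0.15 for FUS1 and 0.18 for STE12, neither past the threshold (adjusted p = 0.462 and 0.724), against 6.64 for ASP3-4 and 3.91 for DSE1. Of 6230 genes, 1987 (31.9%) varied more than the residual noise of the 6 paired arrays. The median SD was 0.29 beside a median noise SD of 0.12, and 297 genes had an SD of at least 1. Within slides 1150 genes passed, all of them among the 1987; 2969 genes (47.7%) had a slide effect. The noise rests on 3 strains: 1832 genes passed without S96, 800 without HS959 and 449 without SEG8.

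The 15 genes with the largest SD ranged over more than 12 log2 units each, mostly from levels near those of S96 to levels near background. After ASP3-4, the SD was 6.59 for ASP3-3, 6.57 for ASP3-1, 6.52 for ASP3-2, 6.32 for REE1 and 6.22 for PRM8. UIP3 (5.98) and the peroxisomal membrane gene PEX30 (5.79) were not well above background on 17 arrays each. YIL082W (5.59) and YIL082W-A (5.49) are Ty element reading frames, and YIL082W did not pass within slides (adjusted p = 0.0512). The aquaglyceroporin gene AQY3 (5.48), CSS3 (5.39), the enterobactin transporter gene ENB1 (5.38), YJL218W (5.31) and the acetyltransferase gene AYT1 (5.26) completed the list. For AQY3, CSS3 and ENB1 both parents were above background, and 18, 13 and 13 segregants fell more than 8-fold below both. AMN1 had an SD of 0.40 (adjusted p = 0.0350) and did not pass within slides (adjusted p = 0.0575) or without any of the 3 strains (adjusted p = 0.0554 to 0.0871), and FLO8 did not pass (SD 0.30, adjusted p = 0.0985). PRM8 did not pass without SEG8 (adjusted p = 0.0587), and YIL082W and YIL082W-A did not pass without S96 (adjusted p = 0.0684 and 0.0618) or without SEG8 (adjusted p = 0.0689 and 0.0659).

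**Figure D2:**
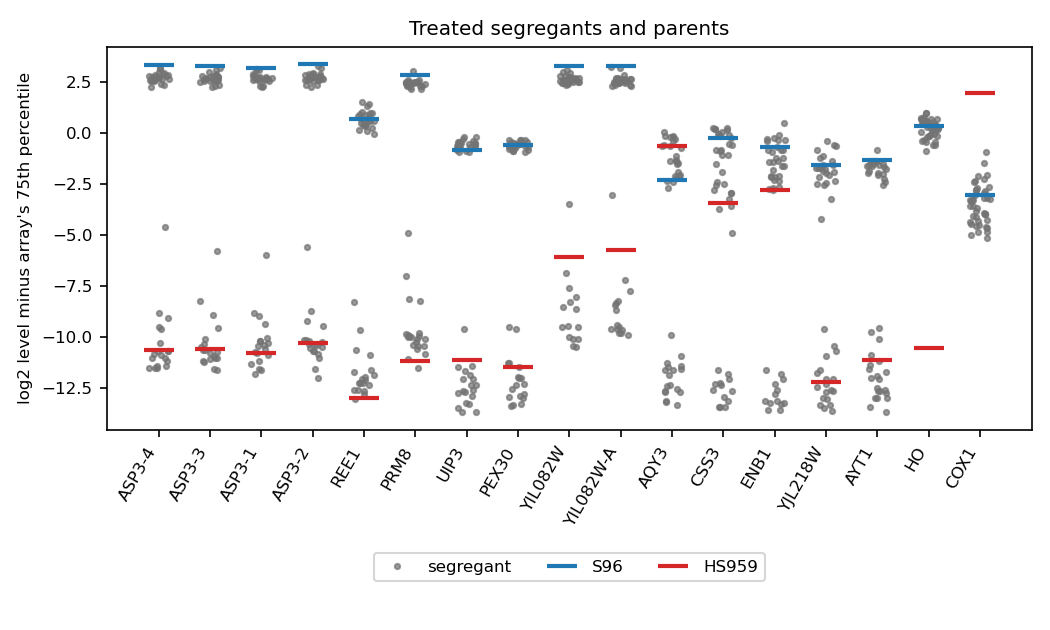
Levels of the 15 most variable genes, HO and COX1 in 43 treated segregants (points) and in treated S96 and HS959 (bars); the vertical axis is log2 intensity minus the 75th percentile of the array, and points are spread sideways for legibility. Segregants divide between high and low levels for genes such as REE1, whereas for HO and COX1 all 43 lie nearer to S96.

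By list, 3 of 39 pheromone-induced genes varied, PRM7 (SD 0.97), PRM8 and PRM9 (4.21), fewer than among other genes (two-sided Fisher's exact test, adjusted p = 0.00244), and also 3 when adjusted over the list alone. The noise also holds strain differences in the response to alpha factor, so such genes can be harder to call (noise SD 0.21 for STE12 and 0.13 for FUS1, median 0.12). The list's median SD among segregants was 0.20, beside 0.29 for all genes. Among signalling components 2 of 21 varied, DIG2 (0.52) and STE50 (0.27), and 1 over the list alone, and 0 of 7 a-specific genes did. The daughter-cell genes varied in 9 of 11 cases, 10 over the list alone (exact adjusted p = 0.00398), with DSE1, DSE2 (2.93), SCW11 (1.42) and BUD9 (1.14) the most variable. Iron uptake genes varied in 11 of 13 measured cases, 12 over the list alone (exact adjusted p = 0.00140), led by ENB1, FIT2 (1.42), FRE5 (1.14) and FIT3 (1.00). Meiosis genes varied in 10 of 12 cases, also 10 over the list alone (exact adjusted p = 0.00244), led by the chromosome axis gene HOP1 (1.5), SPR3 (1.05), REC8 (0.99) and NDT80 (0.90). Only 1 of 138 ribosomal protein genes varied, RPS9A (0.28), and 0 over the list alone, and 5 of 42 ribosome biogenesis genes did, with 0 over the list alone and 1 within slides. Fisher's test treats the genes of a list as independent, which genes regulated together are not, so its p-values are too small for such lists. This applies to the p-values given above as well, and none is given for the 2 ribosomal lists. The general stress list, with 14 of 27 variable, and the remaining 14 lists did not differ from other genes past the threshold, and of the general stress genes HSP12 had an SD of 1.94.

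All 43 treated segregants had a pheromone-induced score, the mean level over the list, above that of all 3 untreated arrays (0.77 to 1.72, against -1.42 to -1.17 untreated). The signalling and a-specific scores were also above the untreated range in 43 segregants, and the G1/S and core histone scores were below it in 43. The alpha-specific score was above it in 39 and the iron uptake score below it in 36, but the phosphate starvation score was below it in 17 only, and the general stress score was above it in 24 and below it in 14. Across segregants, the pheromone-induced score was set against 18 other list scores, and 0 passed after adjustment. The strongest relation was with the ribosomal protein score (Pearson r = 0.36, permutation p = 0.0174, adjusted p = 0.313; Spearman rho = 0.39, permutation p = 0.0098, adjusted p = 0.176). It was 0.41 within slides (adjusted p = 0.107), 0.27 without the 2 segregants farthest from the median, and -0.05 with quantile scaling. The sign differed by slide: r was -0.42 and -0.19 on slides 2 and 5, and 0.62, 0.60 and 0.87 on slides 3, 4 and 6. The daughter-cell and flocculin scores fell into separate clusters of segregants, so no pooled correlation with them is given.

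For each gene that differed between the parents by at least 1 on the log2 scale, segregants were counted as nearer to treated HS959 or to treated S96, which asks whether the cross divides evenly between the parental levels. Over 480 such genes the median was 19 of 43 segregants (44.2%) nearer to HS959. Of these, 103 genes departed from an even division by an exact binomial test after adjustment, 77 toward S96 and 26 toward HS959. For 10 genes 0 of 43 segregants lay nearer to HS959 (exact binomial p = 2.27e-13). They were the mitochondrial COX1, COX2, COB, ATP6, ATP8, BI2 and AI5_ALPHA, the mating-type endonuclease gene HO, and YCR041W and YCR097W-A. MATALPHA1 and HMLALPHA1, whose sequences come from the mating-type loci, had 1 segregant each and the mitochondrial AI5_BETA had 2. At the other end, 41 segregants lay nearer to HS959 for UPC2, a regulator of sterol genes, and 39 each for SRL3 and BSC5. The median was 0 for the 10 mitochondrial genes, with BI3 the highest at 21, and 20 for the 470 nuclear genes. A median of 7.5 segregants lay in the middle when the distance between the parents was cut into 3 equal parts.

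**Figure D3:**
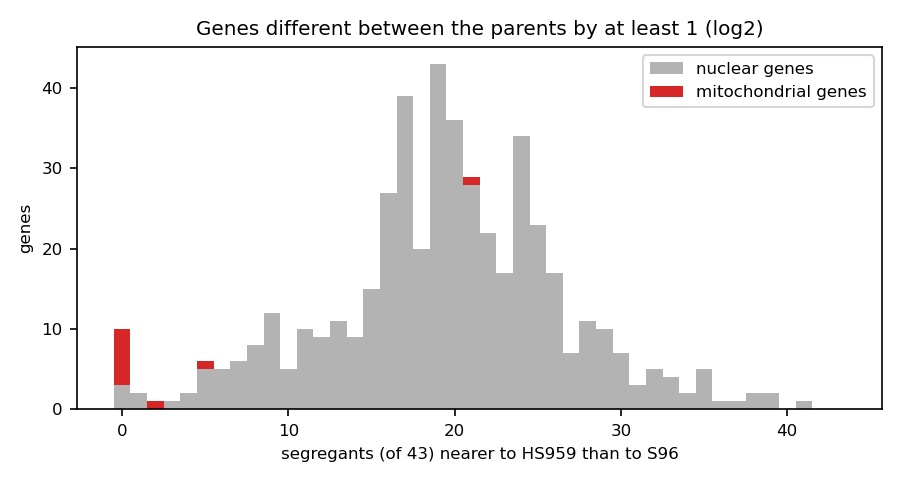
Number of genes, out of 480 that differed between the parents by at least 1 on the log2 scale, by the number of 43 treated segregants whose level lay nearer to HS959 than to S96; bars stack nuclear and mitochondrial genes. The nuclear median is 20, and the mitochondrial median is 0.

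The mean of the segregants was compared with the mean of the treated parents, which asks whether the cross as a whole lay away from the middle of its parents. Of 6230 genes, 2 passed in limma, both higher in the segregants. HO averaged 0.21 ± 0.45 in the segregants (SD, n = 43), with 0.31 in treated S96 and -10.56 in treated HS959, a difference of 5.33 from the parental mean (adjusted p = 0.00173). The mitochondrial intron reading frame AI5_ALPHA averaged -0.22 ± 0.90, with 0.15 in S96 and -11.20 in HS959, a difference of 5.30 (adjusted p = 0.0322). At an unadjusted p under 0.05 there were 378 genes (6.07%). With slide as a block, which sets the parents against the 4 segregants on their slide, the differences were 5.34 and 5.65 and 0 genes passed (adjusted p = 0.0760 for both); AI5_ALPHA also did not pass with normexp background (4.08, adjusted p = 0.132).

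Neighbouring genes varied together among the segregants. The mean Pearson r of adjacent genes was 0.114 over 6193 pairs, against 0.025 for genes on different chromosomes. It was 0.071 for genes 2 apart, 0.054 for 5, 0.048 for 10, 0.051 for 20 and 0.058 for 50, each above all 1000 random gene orders (p = 0.001, the smallest these can give). These correlations are across genes and pairs that share genes, which are not independent. Without the 3 segregants with a shifted chromosome, described next, the mean r of adjacent genes was 0.091.

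In 3 segregants the genes of 1 chromosome lay together above or below the median of all segregants. In SEG9 the median shift of 540 genes on chromosome 12 was 0.79 (1.73-fold), and in SEG42 it was 0.80 (1.74-fold). In SEG45 the median shift of 172 genes on chromosome 3 was -0.95 (0.519-fold). Between 87.4% (SEG42) and 96.5% (SEG45) of the genes on these chromosomes moved in the direction of the median, and the next largest shift of another segregant was 0.152 in size on chromosome 12 and 0.154 on chromosome 3. No other nuclear chromosome of a treated segregant met the rule, and of the 5 other arrays untreated S96 met it for chromosome 1 with a shift of 0.30. When shifts were taken from the mean of the treated parents, the rule was met 4 times in total among treated segregants, beside 3 here.

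**Figure D4:**
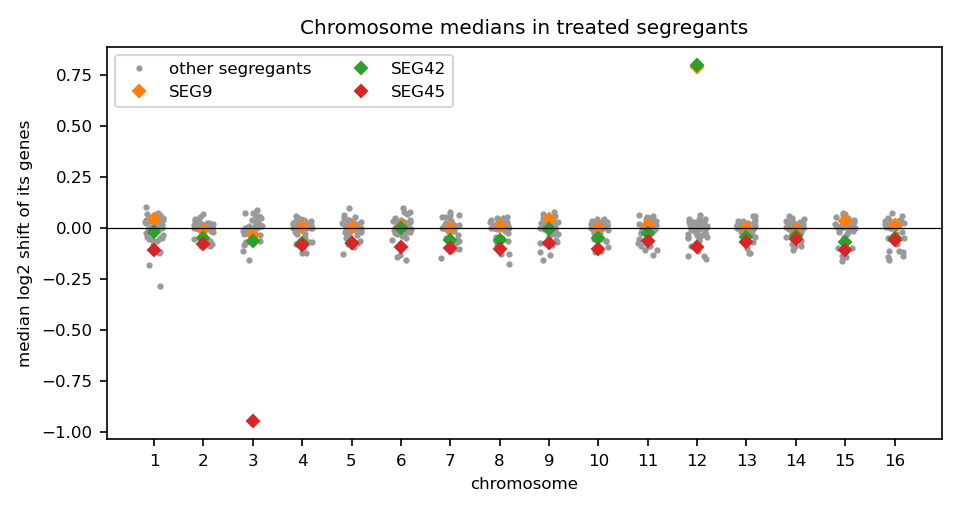
Median log2 shift of the genes of each of 16 nuclear chromosomes (horizontal axis) in each of 43 treated segregants, relative to the median of all segregants. Chromosome 12 of SEG9 and SEG42 lies at 0.79 and 0.80 and chromosome 3 of SEG45 at -0.95, apart from all other points.

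A pair of segregants, SEG15 and SEG17, and another pair, SEG43 and SEG48, had nearly the same profile. Their centred correlations across genes were 0.950 and 0.944, against 0.552 for the next of 903 pairs, and they took the same parental side for 96.9% of 160 genes. The median over pairs was 55%, but SEG41 took the same side as SEG43 for 88.1% and as SEG48 for 88.8%. Between SEG15 and SEG17 32 genes, and between SEG43 and SEG48 22 genes, differed by over 2-fold, against a median of 544 over pairs. HSP30 (3.55) and the iron oxidase gene FET3 (1.73) were among them in the pair of SEG43 and SEG48. Whether each pair was 1 strain could not be told from the arrays alone. They were kept as separate samples, as named in the labels, and with each pair averaged 2091 genes varied among 41 segregants.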

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

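The opposite signs given here were found by reading the treated and untreated arrays of each parent, and no test of them was chosen before or after the values were seen. With 1 pair of arrays per strain the difference between the responses of S96 and HS959 was not tested, for any gene or list named here. Each value is the log2 response of HS959 to alpha factor minus that of S96, for results where the sign was opposite in the 2 parents.

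Among gene lists, the difference was -2.83 for the flocculin genes (0.13 in S96, -2.70 in HS959), -0.48 for the daughter-cell genes, -0.33 for the ribosomal protein genes and -0.16 for the cell wall integrity genes. FLO11, within the flocculin list, differed by -3.28, with 0.02 in S96 and -3.26 in HS959. The Ty reading frames YIL082W and YIL082W-A differed by -5.27 and -4.94, with increases of 3.86 and 3.48 in S96 and changes of -1.40 and -1.45 in HS959. PRM8 differed by -5.06, with 4.14 in S96 and -0.93 in HS959, where its level was low, and PRM9 differed by 1.62, with HS959 not well above background.

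Several further genes had low levels in HS959: HO differed by -1.24, AI5_ALPHA by -2.32, UIP3 by -1.32, PEX30 by -0.45, ASP3-4 by -0.32, ASP3-1 by -0.40 and ASP3-3 by -0.25. Of the rest, CSS3 differed by -1.27, COX1 by -0.37, YER187W by 1.07, COS12 by 1.38 and SNZ3 by 0.43.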

How the results depend on the processing

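The alternatives that averaged near-identical pairs, left out slide 5, left out the 3 segregants with a shifted chromosome or left out genes absent from the reference table were chosen after seeing the data; the others were fixed earlier. Over 28 alternatives and 104 results no called gene, list or shift changed sign. The correlation of the pheromone-induced and ribosomal protein scores, which was not called, went to -0.05 with quantile scaling. Of values for named genes, lists and shifts, 812 kept their side of the threshold or moved by less than their spread, 77 lost their call and 4 moved. Where values changed, the cause was not tested unless fewer arrays or a higher threshold were part of the alternative. Leaving out each strain in turn gave 610 to 1636 genes changed by alpha factor (251 to 743 higher, 359 to 893 lower; without HS959 842, with 379 higher and 463 lower) and 449 to 1832 variable genes (800 without HS959). Without SEG8, 738 genes differed between the parents, 207 higher and 531 lower. With no strain term, and so without pairing the arrays of a strain, 657 genes changed with alpha factor, 320 higher and 337 lower; CSS1, HPF1, STE12, AMN1, FLO8 and the phosphate list lost their calls, and no other named gene or list did. Quantile scaling gave 706 genes higher in HS959 and 608 lower, so that the larger group was the higher one. No count is given for the treated parents against the segregants' spread, which had 1 array per parent and a spread that holds their own difference. Variable genes numbered 1150 within slides, 1167 without slide 5 and 6056 with 1 common noise variance. Genes whose segregant mean differed from the parents numbered 1 with normexp background, 0 with slide as a block and 1 with near-identical pairs averaged. With an estimated correlation, where camera had 2 residual degrees of freedom, 0 lists were called for alpha factor and 0 between the parents. Between the parents fry called 5 lists, iron uptake among them. It lost the parental filamentation, flocculin, ribosomal protein, ribosome biogenesis and ergosterol lists, and the general stress and phosphate lists for alpha factor. With a log2 difference of at least 2, 30 genes departed from an even division between the parents. In SEG9 and SEG45 the chromosome shifts were 0.73 and -0.77 with quantile scaling. Signal over background limits the genes not well above background in a strain, whose changes there are bounds or values of dim probes. The brightest-probe alternative and a slide block in the 6-array fit were not run.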

Other observations

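The tests of shared drop-out of neighbouring probes, of a share of 1 in 4, of the nuclear genes in HS959, of other chromosomes in the same arrays, of chromosome arms, of genes low in HS959 in SEG45 and of the shared mitochondrial shift were chosen after the results were seen, and the other tests weighed here before.

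Some groups without a call as a list held strong changes with alpha factor. Of 15 cell wall integrity genes, 5 rose and 1 fell (mean 0.09 ± 0.18, SD over strains, n = 3; limma camera adjusted p = 0.579): the chitin synthase gene CHS1 rose by 1.83 ± 0.26, the glucan synthase gene GSC2 by 1.29 ± 0.41 and the kinase gene SLT2 by 1.06 ± 0.43, while the mannoprotein gene CWP1 fell by 2.03 ± 0.56. Of 11 filamentation genes, 3 rose and 4 fell (mean -0.37 ± 0.36, adjusted p = 0.804); the pectinase gene PGU1 rose by 2.45 ± 0.53 and the transcription factor gene TEC1 by 1.20 ± 0.35, and SVS1 fell by 2.11 ± 0.92. Of 11 daughter-cell genes, 3 rose and 0 fell (mean 0.24 ± 0.38, adjusted p = 0.242), SCW11 by 1.61 ± 0.10, AMN1 by 1.25 ± 0.15 and CTS1 by 0.59 ± 0.27. Of 19 ergosterol genes, 2 rose and 6 fell (mean -0.13 ± 0.12, adjusted p = 0.630), with ERG24 up by 1.26 ± 0.13, and ERG4 fell by 1.07 ± 0.22. Of 37 amino acid synthesis genes, 4 rose and 5 fell (mean 0.01 ± 0.05, -0.01 with quantile scaling, adjusted p = 0.630), with ARG4 at 1.29 ± 0.07 and LYS20 at -1.16 ± 0.10. Of 15 M/G1 genes, 3 rose and 3 fell (mean -0.12 ± 0.16, adjusted p = 0.891), with CDC6 at -0.94 ± 0.20 and MCM5 at 0.56 ± 0.06. Of 34 respiration genes, 5 rose and 1 fell (mean 0.01 ± 0.02, -0.04 with quantile scaling, adjusted p = 0.429), with CYC1 at -1.05 ± 0.68 and LSC2 at 0.60 ± 0.12. Of 5 flocculin genes 1, FLO10, rose (0.75 ± 0.22; list mean -0.81 ± 1.64, adjusted p = 0.891).

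Between the parents, lists without a call also held large single differences. The siderophore transporter gene ARN2 differed by -9.50 (HS959 minus S96, limma adjusted p = 0.000405) and FIT2 by -2.15 (adjusted p = 0.0205), whereas ARN1 differed by 1.11 (adjusted p = 0.0238); of 14 iron uptake genes 3 were higher and 5 lower in HS959. The meiotic genes HOP1 (2.74, adjusted p = 0.00215) and IME1 (-2.28, adjusted p = 0.000972) differed in opposite directions, with 4 of 12 higher and 4 lower (list mean -0.09, but upward in camera and 0.25 with quantile scaling). The heat shock gene HSP12 differed by 2.01 and HSP104 by -1.23. Of the alpha-specific genes, STE3 differed by -2.60 (adjusted p = 0.00479) and MF(ALPHA)2 by 2.54 (adjusted p = 0.0231). Of core histone and a-specific genes 0 passed. Of 19 G2/M genes CLB2 (0.71) was higher and ALK1 (-1.18) lower, of 15 M/G1 genes CLN3 (0.64) was higher and EGT2 (-1.03) lower, and of 15 cell wall genes CHS3 (0.53) was higher. In segregants, HSP30 exceeded both treated parents by more than 8-fold in 13 of 43, the drug transporter gene AZR1 in 12 and RTA1 in 5. The parental and alpha factor calls shared 468 genes, beside 459 for independent lists, and these comparisons share arrays.

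Of the 10 splits of the 6 arrays into 3 and 3 with strain in the fit, 1, the real one, gave 2223 genes changed by alpha factor and the highest other gave 0; 10 splits are too few for a share under 0.05.

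On slide 5, which held 8 segregants, mitochondrial VAR1 was lower than on the other slides by the value -4.20 and PEX30 higher by 4.11. PEX30 varied about as much within slides (SD 5.75) as over all segregants (5.79), so its difference may reflect which segregants lay there. With slide labels shuffled among segregants, 1 of 100 draws, the real one, gave as many as 2969 genes with a slide effect, and the highest other gave 176. The slide 5 deviation correlated with coding length across 5745 genes (Spearman rho = 0.14), and genes are not independent replicates. Such a relation was not particular to slide 5: rho was -0.12, -0.01, -0.19 and -0.14 for slides 1 to 4 and 0.10 for slide 6.

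The whole-chromosome shifts in SEG9, SEG42 and SEG45 were weighed against uneven arrays, a parental difference and a change in copy number. An uneven array or scaling is argued against, since the largest shift of any other nuclear chromosome in these arrays was 0.109, and so is a difference between the parents along the chromosome, since the treated parents differed by at most 0.0934 in median on chromosomes 3 and 12. The shift ran along both arms, the smallest arm median being 0.781 in size. The hypothesis of 1 chromosome copy more in SEG9 and SEG42 and 1 fewer in SEG45 predicts a shift along both arms. The size of the shift was not tested. If RNA followed copy number, 1 copy more in a haploid would read 2-fold, whereas SEG9 and SEG42 read 1.73-fold and 1.74-fold. A haploid with 1 copy fewer would have none, whereas chromosome 3 of SEG45 read 0.519-fold. For SEG45 the hypothesis therefore needs 2 copies of its other chromosomes, against the haploid state given for these strains. For SEG45, 1 copy of its other chromosomes from each parent is argued against: of 33 genes off chromosome 3 and at least 6 log2 lower in treated HS959 than in S96, 20, on 8 chromosomes, lay over 8-fold below S96 in SEG45 (60.6%), among them REE1 and YJL218W, although the share of genes in the middle of 3 equal parts between the parents (16.9%, median of segregants 13.1%, highest 19.4%), looked at earlier, did not decide. Copies of the other chromosomes from the same parent were not tested, and DNA was not analysed here.

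Some genes were near background in part of the segregants although well above background on every parent array. A gene is called lacking where it lay over 8-fold below both treated parents. There were 11 such genes, all within 20 genes of a chromosome end, as are 10.3% of nuclear genes. Defective spots are argued against, because 100% of the 18 segregants lacking any of AQY3, AGP3 and ZNF1 lacked all 3, and SEG8 lacked AQY3 on both its arrays. For dim arrays that share could not decide, since they would lower all 3 together. Seen afterwards, only 6 of the 18 also lacked ENB1, and at least 94.0% of gene spots were well above background on every array, which argues against dim arrays. A candidate explanation is that the parents carry these stretches at different, unlinked places, so that 1 in 4 segregants inherits none. For ENB1, 13 of 43 lacked it, the same 13 as for CSS3 (30.2%, exact 95% interval 17.2% to 46.1%, exact binomial p = 0.480), so that share stays open. By the same test ADH7, AAD3 and YCR102C, each lacking in 9 segregants (20.9%), gave p = 0.602, and COS12, lacking in 6, gave p = 0.113. COS7, lacking in 5 (11.6%), gave p = 0.0509. Its level was -8.75 in treated HS959 against -2.68 in treated S96. Whether HS959 carries it is unclear, so its share cannot decide on copies in both parents. For AQY3, 18 of 43 lacked it (41.9%, exact 95% interval 27.0% to 57.9%), which departs from 1 in 4 at exact binomial p = 0.0203 but not after adjustment over the 11 genes (p = 0.0743).

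HO and 7 mitochondrial genes lay nearer to S96 in all 43 segregants. The nuclear YCR041W and YCR097W-A did so too, and explanations for them were not weighed here. HS959 arrays from a strain unrelated to the cross are argued against, since over nuclear genes the median was 20 of 43 segregants nearer to HS959. Inheritance of 1 stretch around HO stays open. The 5 called genes within 20 genes of HO had a median of 17 nearer to HS959. That median could not decide, since their counts went both ways, from 4 for YDL241W to 31 for YDL240C-A. Slide differences in mitochondrial RNA as a whole are argued against for the 5 genes higher in HS959. Each segregant's shared shift (-3.95 to 0.14, median -1.51) was taken from 8 mitochondrial genes that did not differ between the parents. With it removed, 2.79% of the values of those 5 genes lay nearer to HS959. The genes had been picked because 0 of 43 segregants lay nearer to HS959 before the removal. AI5_BETA, COX3 and BI3, with 2, 5 and 21 segregants nearer to HS959, were left out, so the share says nothing about them. For AI5_ALPHA and ATP6, which were lower in HS959, the share was 0%. That share could not decide, since removing a mostly negative shift raises their levels away from HS959. An earlier look at the 4 segregants on the parents' slide (10% of 40 values of 10 mitochondrial genes) did not decide, and slide effects on single genes were not tested. Inheritance of mitochondria from S96 alone, or a parent of the cross that differed from HS959 at HO, may also account for the pattern, and neither was tested.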
